A study of Mus musculus with 28 samples.

How the data were processed

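Chromatin accessibility was measured by ATAC-seq, which cuts open chromatin with a transposase and sequences the released fragments, in 28 mouse libraries of 14 groups with 2 libraries each. Per the labels' protocols, 60000 cells entered each reaction, libraries were amplified for 13 PCR cycles and fragments of 100 to 1000 bp were kept. Nothing in the labels says whether the 2 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

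The deposited files were other data than counts or signal: per the submitters' processing notes the authors used BWA and HOMER with the mm9 mouse genome, and each deposited list holds the chromosome, start and end of the peaks called in 1 library, with no score, height, p-value or read count. Versions of these tools, the peak threshold, read filters and any shift of reads for the transposase cut are not given in the sources used here. Peaks were thus called per library and not on pooled samples, as far as the lists show. Sequencing depth per library is unknown from the lists, and no interval that needs read numbers is given. Positions on chromosome 1 reached 197068386, and starts were read as counted from 0 and are printed counted from 1.

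The lists held 37301 to 134997 peaks. In every list but that of MEF10 MyoD+FRG replicate 2 most peaks shared 1 width, and that width differed between lists, from 61 bp in an FRG library to 205 bp in a Dox+FRG day 2 library, with 500 bp in MEF10 MyoD+FRG replicate 2. That last list had a median width of 722 bp, peaks of up to 202465 bp, and covered 92.9 Mb. No peak was left out, and no list held peaks on chromosome Y.

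Peaks of all 28 libraries that overlapped by at least 1 bp were merged into 253225 regions, and a library called a region when it had a peak in it. For each comparison a region was gained when both libraries of the first group and neither of the second called it, and lost in the reverse case. With 2 libraries against 2 there are 3 splits, so an exact p cannot go below 0.333, and the counts are set beside those that follow the other splits of the same 4 libraries. Replicate similarity was the Jaccard index (shared regions over regions called in either library), tested by permuting library labels 100000 times, one-sided. Relations with day used Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples. The smallest p these can give is 1e-05. These choices were made before the data were examined.

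Further measures were chosen after the lists had been seen. Regions were classed by the day 0 fibroblasts and the satellite cells: 16652 fibroblast-only regions (both day 0 libraries, no satellite cell library), 7314 activated-only and 5637 quiescent-only regions (both libraries of that satellite cell group, neither of the other and no day 0 library), 3119 satellite-shared regions (all satellite cell libraries, no day 0 library) and 19407 common regions. Class shares were compared in 7 two-sided exact permutation tests with Benjamini-Hochberg adjustment. Gained and lost regions were also counted in 100 kb windows with at least 5 regions, a region being placed by its middle, each window tested by a one-sided Fisher's exact test against all regions called in both libraries of either group, with Benjamini-Hochberg adjustment over windows and directions. The windows named are those past an adjusted p of 0.05 among the 3 with most gained or lost regions of a comparison, and the first of each direction in the comparisons of Dox+FRG day 8 and day 10 GFP with day 0. Neighbouring regions are not independent, so these p-values describe the lists and not replicate cultures.

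Tests of gene lists, motifs, promoter shares and named genes had been planned. They were not run, because the gene table at hand is for GRCm38.p6, another build than mm9, and no mm9 annotation or sequence was used here. The planned use of the highest-scoring peaks was not run for want of a score, and equal list lengths were made by a random draw of 37301 peaks per library. Alternatives planned before were an overlap of at least 50% of the shorter peak, that draw, autosomes alone, and each library left out in turn. Alternatives added after the lists were seen were extended peaks (wider than the most common width of their list, a stand-in for a stricter threshold), a random draw of equal numbers of extended peaks, class shares on the classes of the deposited lists, regions merged from the 4 libraries compared, and regions merged without MEF10 MyoD+FRG replicate 2. The lists give no peak strength, and the width cut was not equally strict across them. In FRG day 8 replicate 1, 42643 of 134997 peaks were wider than 61 bp. In Dox+FRG day 2 replicate 2, 3272 of 46017 peaks were wider than 205 bp.

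The counting was tested on simulated lists made from 57069 day 0 regions with 200 regions changed each way and a detection of 85.3% per library. It gave 1015 gained and 1055 lost regions where 1033 were expected with chance misses, so most differing regions in that simulation were chance misses. All 4 windows called there were among those planted. This tells of false calls and not of how many planted windows were missed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.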

Results

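Accessible regions were listed for mouse embryonic fibroblasts carrying a doxycycline-inducible MyoD transgene and a Pax7-nGFP reporter, and for satellite cells, the stem cells of skeletal muscle. MyoD is a transcription factor that can turn fibroblasts into muscle cells. The MEF14 groups were day 0 fibroblasts, cells given doxycycline with forskolin, RepSox and the GSK3 inhibitor CHIR99021 (Dox+FRG) for 2, 4, 6 or 8 days, Dox+FRG cells labelled GFP at days 8 and 10, cells with doxycycline alone (Dox) at days 4 and 8, and cells with the small molecules alone (FRG) at day 8. FRG was read as the initials of the small molecules. The MEF10 groups were labelled MyoD+FRG and MN+FRG at day 6, and MN is not defined by the labels. Each of the 14 groups, quiescent and activated satellite cells included, had 2 libraries. Lists without a GFP label are called unsorted here, although the labels do not state which cells were sorted.

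The lists held between 37301 peaks (MEF10 MyoD+FRG replicate 1) and 134997 peaks (FRG day 8 replicate 1), with the longest lists in the Dox and FRG groups. Libraries of 1 group shared more regions on average than other libraries did. The Jaccard index was 0.693 ± 0.103 (SD, n = 14 pairs) within groups and 0.429 on average over the 364 other pairs, a difference of 0.264 (one-sided permutation test, p = 1e-05, the smallest it can give). MEF10 MyoD+FRG stood apart with an index of 0.380 between its libraries. The closest library was the own replicate for 24 of 28 libraries, and for neither MEF10 MyoD+FRG library. Dox+FRG day 4 replicate 1 was closer to a day 6 library (0.675) than to its replicate (0.647). The same held for Dox+FRG day 8 replicate 1 (0.715 and 0.673). Dox+FRG day 8 GFP and day 10 GFP libraries had a mean index of 0.659 with each other, against 0.566 and 0.591 with unsorted day 8 cells.

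Which of the gained and lost counts was larger changed when the lists were cut to equal numbers of peaks. With the same number of peaks drawn at random from each list it turned in all 15 comparisons, and with the same number of extended peaks (wider than the most common width of their list) in 12 of the 15. With extended peaks as listed it turned in 1, and with autosomes alone, a stricter overlap or regions merged from the 4 libraries compared in 0. A random draw takes away a larger part of a long list, strong peaks included. Regions called in all 4 libraries are then missed more often in the longer lists and can count as gained or lost. The turn can thus come from the draw itself, and neither set of counts is corrected for depth. For this reason each pair of gained and lost counts is followed by the pair from lists of equal length. Leaving out a library lets 1 library stand for its group, which raises counts by construction, and the values are given where a count moved by over 1.5 times.

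**Figure D1:**
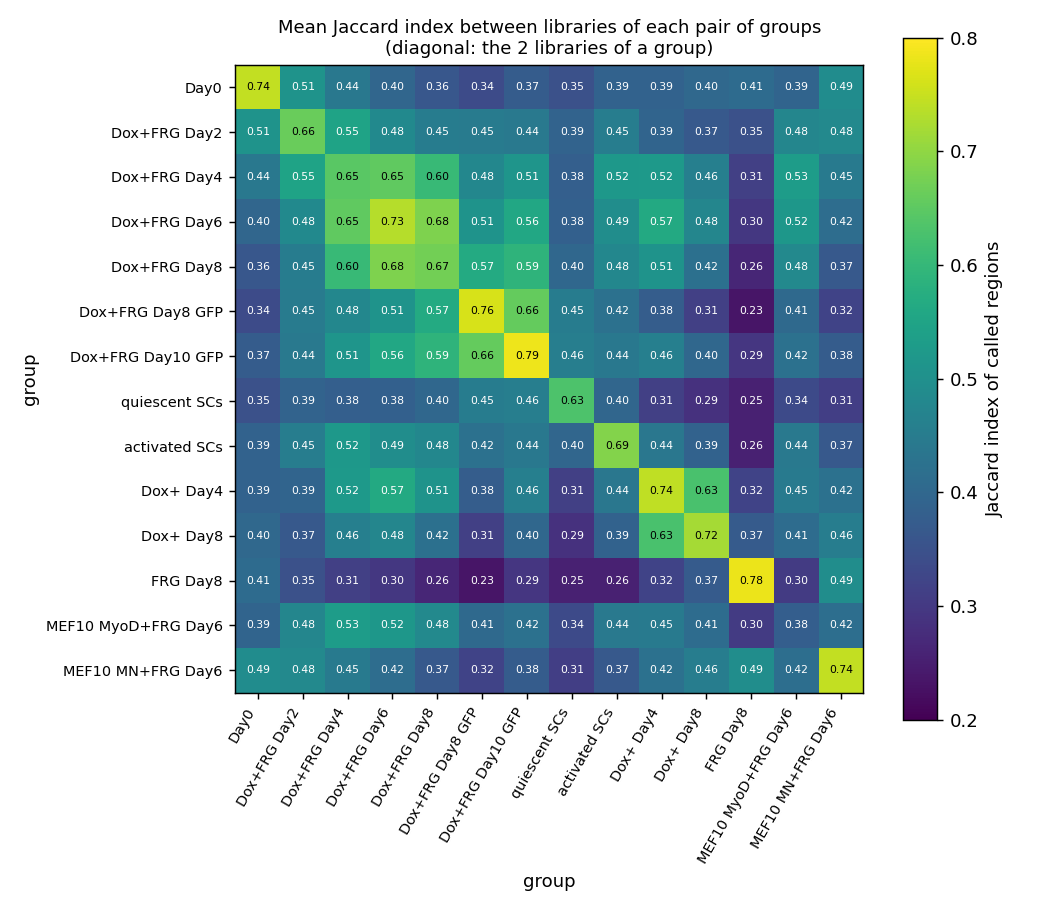
Mean Jaccard index of called regions for each pair of groups (color scale and printed values, axes: groups), with the index of a group's own 2 libraries on the diagonal. Within-group values lie between 0.632 and 0.785 except for MEF10 MyoD+FRG at 0.380.

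In unsorted Dox+FRG cells, both day 8 libraries called fewer fibroblast-only and more activated-only regions than both day 2 libraries, a difference that was not tested on its own. Fibroblast-only regions were called at 34.7% ± 9.79 on day 2 and 11.9% ± 4.36 on day 8 (SD, n = 2 each). Activated-only regions went from 19.3% ± 6.25 on day 2 to 57.0% ± 8.67 on day 4 and 55.4% ± 9.09 on day 8, and quiescent-only regions from 7.21% ± 3.37 to 17.0% ± 3.91. Day 8 cells had 14968 gained and 22953 lost regions against day 0. Of the gained regions, 19.1% were called in both libraries by day 2 and a further 43.2% first at day 4, while 50.3% of the lost regions were called in neither library at day 2. The day 2 lists held 59721 and 46017 peaks and the day 0 lists 70756 and 67502. These shares come from the deposited lists, so shorter day 2 lists may account for part of the early losses. A further 3335 regions were called in both libraries at day 2, 4 or 6 and in neither at day 0 and day 8. Conversely, 1927 regions were called in both libraries at day 0 and day 8 and in neither at day 2, 4 or 6. The 37921 differing regions compare with at most 1241 following another split of the same libraries. With equal list lengths the day 8 balance turned, to 9339 gained and 8605 lost regions, and without Dox+FRG day 8 replicate 2 to 26619 gained and 23842 lost. Against day 0, the earlier days had 5008 gained and 14837 lost (day 2), 11770 and 16096 (day 4), and 17462 and 19836 (day 6) regions. These balances turned as well with equal list lengths, to 6768 and 5966 (day 2), 7761 and 7314 (day 4), and 8679 and 8343 (day 6). Gained and lost regions were 12190 and 16568 without day 2 replicate 2 and 6161 and 23046 without day 0 replicate 2 at day 2, and 13917 and 24505 without day 4 replicate 1 at day 4. The day 4 balance also turned without day 4 replicate 2 (22337 gained and 17070 lost), and the day 6 balance without day 6 replicate 1 (23371 and 22379) or replicate 2 (23282 and 22740).

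The window with most gained regions at day 8 lay on chromosome 7 from 6700001 to 6800000 in mm9, with 9 of 14 regions gained (adjusted p = 0.335, Fisher's exact test). The one with most lost regions lay on chromosome 10 from 120000001 to 120100000, with 10 of 12 lost (adjusted p = 0.335, Fisher's exact test). No window passed the adjusted threshold by Fisher's exact test in this comparison, against 263 gained and 264 lost windows at an unadjusted p under 0.05. With extended peaks, each window named here and below held at most 1 gained or lost region, so the window results rest on peaks of the most common width.

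The share of activated satellite cell regions called went from 69.3% ± 0.613 at day 0 to 80.1% ± 6.74 at day 4 and 74.2% ± 5.86 at day 8 (SD, n = 2). Over 10 unsorted libraries it had no relation with day past the threshold (r = 0.50, permutation p = 0.145, rho = 0.57, p = 0.0988). Without the day 0 libraries r was 0.30 (permutation p = 0.468), and without the day 8 libraries 0.75 (permutation p = 0.0380). The share of day 0 regions called was 66.1% ± 6.86 at day 2 and 54.3% ± 5.61 at day 8, and over 8 libraries r was -0.68 (permutation p = 0.0605) and rho -0.73 (p = 0.0546). Adjusted over the 2 relations, the p-values were 0.145 and 0.121 for r, and 0.0988 for each rho. Without day 2 r for day 0 regions was -0.65 (permutation p = 0.178) and without day 8 -0.44 (permutation p = 0.422), while with equal list lengths it was -0.84 (permutation p = 0.00845). With the replicate number as a block, r was 0.55 for activated satellite cell regions (permutation p = 0.121) and -0.85 for day 0 regions (permutation p = 0.0312). Whether replicate numbers pair the libraries stays open. Deviations of same-numbered Dox+FRG libraries correlated at 0.109 for days 4 and 8, 0.080 for days 2 and 4 and 0.028 for days 2 and 8. With day 6 the correlations of days 2, 4 and 8 were -0.0047, -0.00052 and -0.00024.

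**Figure D2:**
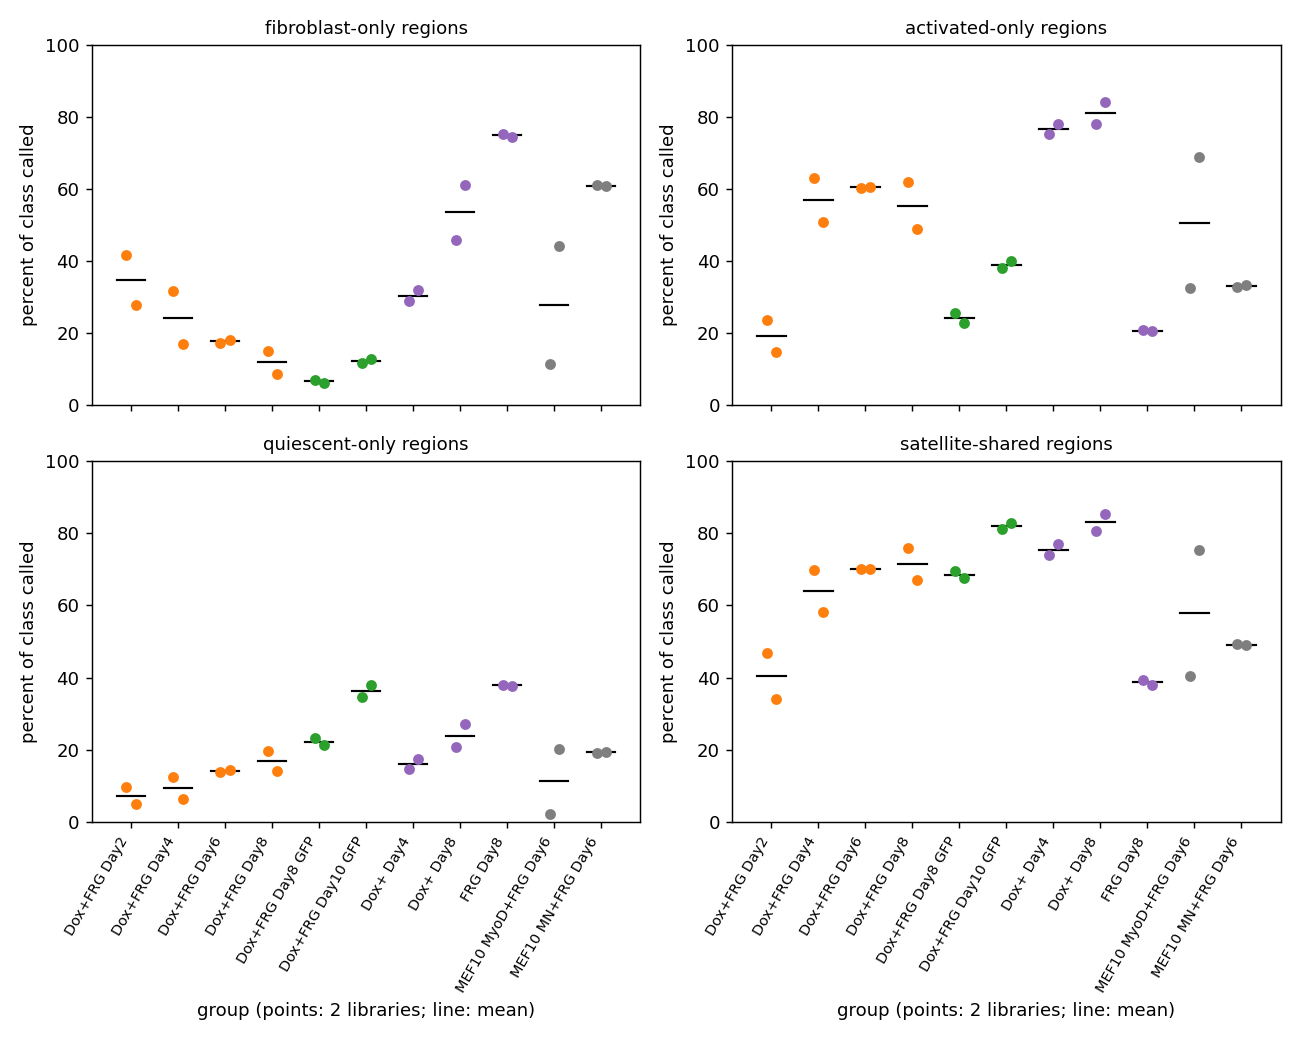
Percent of the regions of each class (y axis) called in each library (points, 2 per group) with the group mean (line), for groups that did not define the classes (x axis). Both GFP groups lie below 40% of activated-only regions and FRG lies near 75% of fibroblast-only regions.

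Cells labelled GFP called quiescent-only and activated-only regions about equally often, while unsorted Dox+FRG cells called activated-only regions far more. At day 8, GFP cells called 22.2% ± 1.34 of quiescent-only and 24.2% ± 1.94 of activated-only regions (SD, n = 2), against 17.0% ± 3.91 and 55.4% ± 9.09 in unsorted cells. At day 10, GFP cells called 36.3% ± 2.36, 39.0% ± 1.39 and 82.0% ± 1.04 of quiescent-only, activated-only and satellite-shared regions. The log2 ratio of quiescent-only to activated-only shares was -0.11 ± 0.03 in 4 GFP libraries of days 8 and 10 and -1.99 ± 0.52 in 8 unsorted libraries of days 2 to 8 (exact permutation test over 495 splits, p = 0.00202, adjusted p = 0.0141), and it was higher in every GFP library than in every unsorted one. The test permuted the 2 libraries of a group as separate units, and days differed between the sides. Unsorted group means were -1.47 at day 2, -2.67 at day 4, -2.11 at day 6 and -1.71 at day 8, where GFP cells had -0.12. Fibroblast-only regions were called at 9.49% ± 3.25 in GFP and 22.2% ± 10.6 in unsorted libraries (exact permutation p = 0.0364, adjusted p = 0.0848), which did not pass after adjustment. Satellite-shared regions were at 75.3% ± 7.87 and 61.5% ± 14.3 (exact permutation p = 0.0970, adjusted p = 0.133). The unsorted libraries included day 2, at 40.4% ± 9.02 of satellite-shared regions, and at day 8 alone GFP and unsorted cells were at 68.5% ± 1.38 and 71.4% ± 6.26 of satellite-shared and 6.73% ± 0.578 and 11.9% ± 4.36 of fibroblast-only regions (SD, n = 2). Day 8 GFP cells had 2685 gained and 9986 lost regions against unsorted day 8 cells, with at most 1940 following another split. With equal list lengths these were 5443 and 5001. They were 4672 and 12709 without GFP replicate 1, 5398 and 11249 without GFP replicate 2, 5795 and 12147 without unsorted replicate 1, and 3316 and 23145 without unsorted replicate 2.

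Regions on chromosome 16 from 11600001 to 11700000 (mm9) were lost in day 8 GFP cells, 7 of 7 (adjusted p = 0.0368, Fisher's exact test). The window on chromosome 9 from 71200001 to 71300000 likewise had 7 of 7 lost (adjusted p = 0.0368, Fisher's exact test). In the chromosome 16 window, activated satellite cells called 9 and 10 regions and quiescent satellite cells 0 in both libraries. Day 10 GFP cells called 3 and 4 regions there, day 0 fibroblasts 3 and 3, unsorted day 8 cells 9 and 7, Dox day 8 cells 16 and 15, and FRG cells 15 and 13.

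Against day 0 fibroblasts, day 10 GFP cells gained 18987 and lost 22932 regions, with at most 801 following another split. Of the gained regions, 37.9% were called in no satellite cell library, 20.0% in activated and no quiescent libraries, 18.0% in quiescent and no activated libraries, and 13.0% in all of them. Unsorted day 8 cells called 61.9% ± 9.44 of these gained regions and Dox day 8 cells 66.4% ± 5.51 (SD, n = 2). Lists of equal length gave 9781 gained and 8854 lost regions, and without day 10 GFP replicate 1 the balance turned to 25125 gained and 24312 lost. The windows with most gained and most lost regions, on chromosome 1 from 39800001 to 39900000 with 9 of 10 gained (adjusted p = 0.0673) and chromosome 4 from 114000001 to 114100000 with 9 of 11 lost (adjusted p = 0.258), did not pass Fisher's exact test. No window did after adjustment, with 407 gained and 288 lost windows at an unadjusted p under 0.05.

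Day 10 GFP cells called 80.3% ± 0.860 of the 36006 quiescent and 72.5% ± 0.862 of the 43464 activated satellite cell regions (SD, n = 2). Day 0 fibroblasts already called 69.8% and 69.3% of these. FRG day 8 cells called 81.5% and 75.0% and Dox day 8 cells 82.1% and 93.3%, from longer lists, so these shares are not particular to GFP cells. Against activated satellite cells they gained 17432 and lost 10678 regions, with at most 889 following another split. Against quiescent satellite cells they gained 17046 and lost 6177, with at most 1305 following another split. With equal list lengths these became 7992 and 8028 against activated, and 7266 and 7532 against quiescent cells, so the balance turned in both. Without activated satellite cell replicate 1 the balance against activated cells turned as well, to 18970 and 20501. Against quiescent cells there were 25749 gained and 6743 lost regions without quiescent replicate 1, and 17257 and 15294 without replicate 2. Against activated cells no window passed Fisher's exact test after adjustment, with 341 gained and 171 lost windows at an unadjusted p under 0.05. Against quiescent cells 1 gained and 19 lost windows passed, among them chromosome 6 from 41000001 to 41100000, 8 of 8 gained (adjusted p = 0.0266), chromosome 12 from 71900001 to 72000000, 9 of 12 lost (adjusted p = 0.00169), chromosome 3 from 27300001 to 27400000, 7 of 10 lost (adjusted p = 0.0115), and chromosome 10 from 19700001 to 19800000, 7 of 9 lost (adjusted p = 0.0115), all by Fisher's exact test.

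Activated and quiescent satellite cells differed in 23880 regions, 14684 gained and 9196 lost in activated cells, with at most 1922 following another split. In all 4 gained and 25 lost windows passed Fisher's exact test. Activated cells alone filled the chromosome 16 window from 11600001 to 11700000, 8 of 8 regions (adjusted p = 0.0248, Fisher's exact test), and the window on chromosome 2 from 113200001 to 113300000, 9 of 10 (adjusted p = 0.0393, Fisher's exact test). Quiescent cells alone had 8 of 8 regions on chromosome 10 from 19700001 to 19800000 (adjusted p = 0.00469, Fisher's exact test), 9 of 11 on chromosome 18 from 55100001 to 55200000 (adjusted p = 0.0102) and 8 of 10 on chromosome 1 from 155000001 to 155100000 (adjusted p = 0.0248). Equal list lengths gave 7999 gained and 8056 lost regions and extended peaks 1116 and 1134. There were 26035 gained and 10100 lost regions without activated replicate 1, and without quiescent replicate 2 the balance turned, to 14802 gained and 21618 lost.

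In the lists as deposited, Dox cells called more activated-only regions than Dox+FRG cells of the same days, and more fibroblast-only regions at day 8 than at day 4. Activated-only regions were called at 78.9% ± 3.79 in 4 Dox libraries and 56.2% ± 7.31 in 4 Dox+FRG libraries of days 4 and 8 (exact permutation test over 70 splits, p = 0.0286, adjusted p = 0.0848), which did not pass after adjustment. Equal list lengths turned this difference, to 6.74 percentage points more in Dox+FRG. A random draw takes a larger part of the longer Dox lists and lowers their shares by construction. This holds for fibroblast-only regions too, so the draws do not decide either difference. Fibroblast-only regions were at 30.4% ± 2.17 on day 4 and 53.5% ± 10.8 on day 8 in Dox cells (SD, n = 2). Over both days they were at 42.0% ± 14.8 in Dox and 18.1% ± 9.64 in Dox+FRG libraries (exact permutation p = 0.0571, adjusted p = 0.100), but Dox+FRG minus Dox was only -2.26 points with equal list lengths, and with equal numbers of extended peaks Dox+FRG was 3.64 points higher. The log2 ratios of fibroblast-only to activated-only and quiescent-only to activated-only shares did not pass either (exact permutation p = 0.114 and 0.686, adjusted p = 0.133 and 0.686). Dox day 8 cells had 42911 gained and 7174 lost regions against day 0, with at most 1781 following another split. Dox+FRG day 8 cells had 1931 gained and 39421 lost regions against Dox day 8, and Dox+FRG day 4 cells 2351 and 20227 against Dox day 4. With equal list lengths these became 5836 and 9419, 9429 and 5170, and 7084 and 5131, so each balance turned. Dox day 8 against day 0 had 65311 and 7950 without Dox replicate 1, 49369 and 11860 without Dox replicate 2, and 46422 and 11995 without day 0 replicate 2. Dox+FRG against Dox at day 8 had 3008 and 52083 without Dox+FRG replicate 1, 5645 and 41119 without Dox+FRG replicate 2, 2255 and 64917 without Dox replicate 1, and 3617 and 46383 without Dox replicate 2. At day 4 these were 3525 and 32684, 8291 and 22000, 3133 and 33219, and 3867 and 27378, in the same order. The window on chromosome 10 from 44800001 to 44900000 had 15 of 15 regions gained in Dox day 8 cells (adjusted p = 0.0197, Fisher's exact test), but 0 with equal list lengths.

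In the lists as deposited, FRG cells called most fibroblast-only regions, and quiescent-only more often than activated-only regions. At day 8 they called 74.8% ± 0.633 of fibroblast-only, 37.8% ± 0.163 of quiescent-only and 20.7% ± 0.280 of activated-only regions (SD, n = 2). The fibroblast-only share was 62.9 percentage points above that of Dox+FRG day 8 cells, 11.9 points with equal list lengths and -3.40 points with equal numbers of extended peaks, where the order reversed. Such draws lower the shares of the longer FRG lists by construction, so they do not decide the difference. FRG day 8 cells had 52096 gained and 5437 lost regions against day 0, with at most 813 following another split, and 5336 and 9584 with equal list lengths. Dox+FRG day 8 cells had 11369 gained and 70505 lost regions against FRG day 8, and 12335 and 6243 with equal list lengths. Without day 0 replicate 2, FRG against day 0 had 57195 gained and 9093 lost regions, and without Dox+FRG day 8 replicate 2, Dox+FRG against FRG had 20609 and 72118.

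The regions gained in Dox+FRG day 8 cells were compared with those gained in Dox and in FRG cells. Of the 14968 gained regions, 12118 (81.0%) were gained in Dox and 3806 (25.4%) in FRG day 8 cells. Independent sets would share 4161 and 4401 regions, and simulated unchanged groups against the same day 0 libraries 872.9. The numbers for independent sets, here and for lost regions, let any of 154345 (Dox) and 177162 (FRG) regions be gained or lost. Regions called at day 0 cannot be gained, and only these can be lost, so the numbers are too low. Lost regions overlapped by 6746 with Dox and 4383 with FRG, where independent sets would share 1067 and 704.4, and simulated groups 24.5. The gained overlap with FRG, 3806, lay below even the 4401 of independent sets. The other overlaps lay above such numbers, but their excess is overstated. Day 0 libraries are too few to split, so part of the excess in the others may come from the shared controls.

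**Figure D3:**
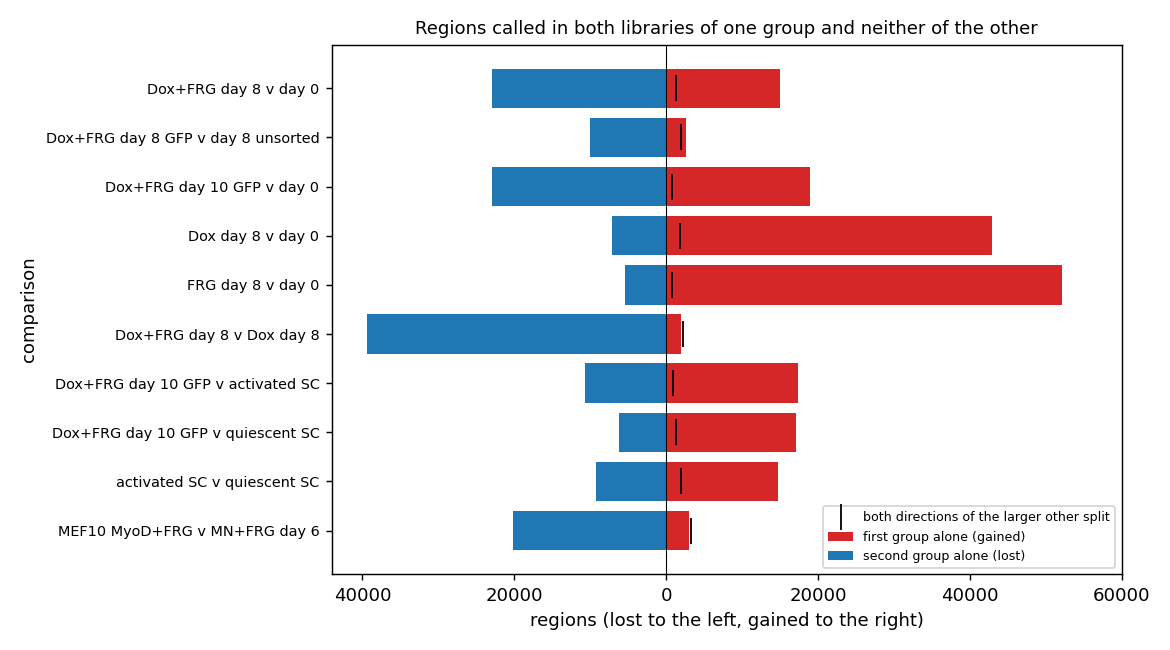
Regions gained (right) and lost (left) in each comparison (x axis, number of regions), with the larger count that follows another split of the same 4 libraries (tick, both directions summed). The largest tick stands at 3324, for MEF10 MyoD+FRG against MN+FRG, beside 3052 gained and 20128 lost regions.

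MEF10 MyoD+FRG and MN+FRG cells differed in 3052 gained and 20128 lost regions, but the MyoD+FRG libraries were far apart. Their activated-only shares were 32.5% and 68.9% and their fibroblast-only shares 11.4% and 44.1%, against means of 33.1% ± 0.464 and 60.9% ± 0.110 (SD, n = 2) in MN+FRG. Replicate 2 covered 92.9 Mb, against 7.85 Mb in replicate 1. At most 3324 regions followed another split. Lists of equal length gave 5856 gained and 5800 lost regions, which turned the balance. The balance turned without MyoD+FRG replicate 1, to 27154 gained and 20537 lost, and the counts were 3400 and 45755 without replicate 2. With an overlap of at least 50% of the shorter peak they were 5731 and 18806. The window on chromosome 8 from 10000001 to 10100000 had 6 of 9 regions gained (adjusted p = 0.00318, Fisher's exact test).

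**Figure D4:**
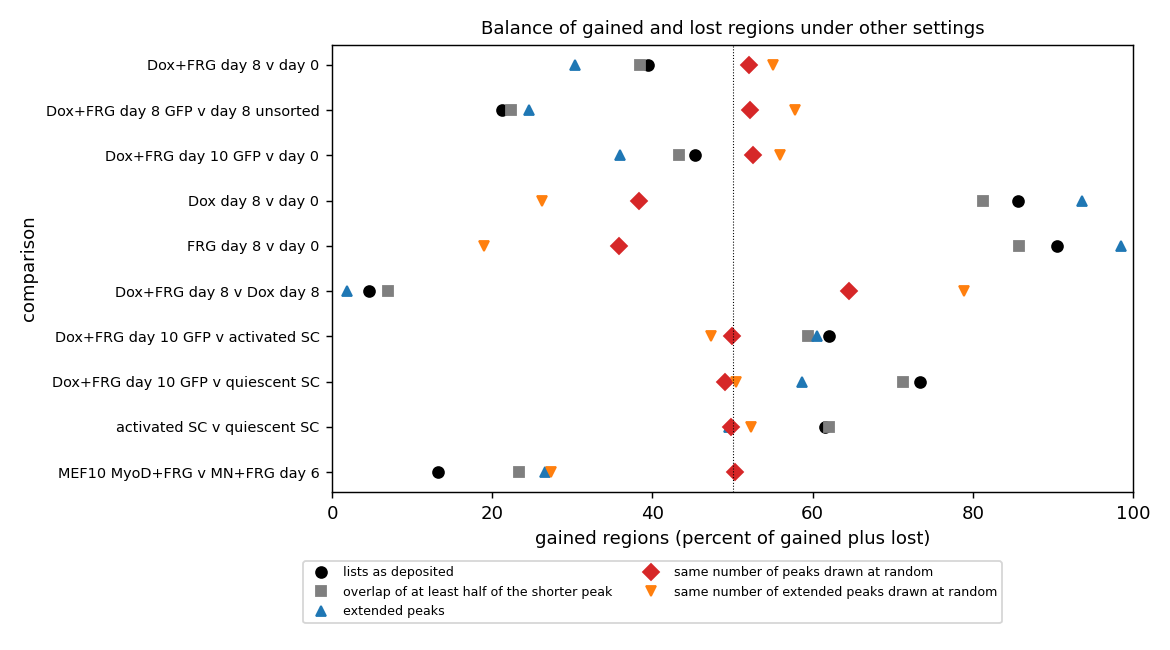
Gained regions as a percent of gained plus lost regions (x axis) in each comparison with the deposited lists and under 4 other settings (symbols). Drawing the same number of peaks from each list puts every comparison on the other side of 50% from the deposited lists.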

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

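The tests of list length, detection and unconverted cells here were chosen after the shares had been seen. The change in fibroblast-only regions from day 4 to day 8 went opposite ways in Dox and Dox+FRG cells. In Dox cells every day 8 library lay above every day 4 library, with a mean change of 23.2 percentage points, and in Dox+FRG cells every day 8 library lay below, with a mean change of -12.4 points. The difference of 35.6 points was not itself tested, and with extended peaks the Dox+FRG changes ranged from -21.5 to 3.41 points, so their direction did not hold for every pair of libraries. The log2 ratio of fibroblast-only to activated-only shares moved the same way, by 0.72 in Dox and -0.97 in Dox+FRG cells, a difference of 1.70, also untested. With extended peaks these were 0.20 and -0.65, a difference of 0.85, and the Dox+FRG changes ranged from -1.45 to 0.14, so again not every pair kept the direction.

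A uniform rise in detection stays open. With extended peaks on the classes of the deposited lists the log2 ratio rose by 1.02 in Dox cells, between 0.65 and 1.39 over the pairs of libraries. This argues against it only as far as peak width follows strength, which the lists do not give. There fibroblast-only regions rose 2.09-fold and activated-only regions stayed at 16.2%. Only 21098 of 89871 peaks in Dox day 4 replicate 1 and 22505 of 108663 in Dox day 8 replicate 1 were extended. The low activated-only share may thus reflect how few peaks were wide, and its distance from a ceiling is not known. The deposited lists do not decide it either, because the 1.76-fold rise of fibroblast-only regions there would have taken activated-only regions from 76.6% to 135%. Equal list lengths (0.53 in Dox, -0.73 in Dox+FRG) thin both classes alike.

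Dox day 8 lists were longer than Dox day 4 lists, so list length is a candidate explanation. With the same number of peaks drawn from each library the Dox change shrank to 3.67 points, still with every day 8 above every day 4 library. With equal numbers of extended peaks the smallest difference between a day 8 and a day 4 library was 0, so list length stays open as part of the cause. A growing share of unconverted fibroblasts in the Dox culture stays open as a biological hypothesis, which would have activated-only regions fall. They rose by 4.55 points in the deposited lists, which calls that saturate at high accessibility would also allow, and by 8.48 with extended peaks. The change was -4.09 points with equal list lengths (-6.73 to -1.44 over the pairs of libraries) and -0.745 with equal numbers of extended peaks. A random draw takes more from the longer day 8 lists, so the sign does not decide the question.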

How the results depend on the processing

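Extended peaks, equal numbers of extended peaks, merging from the 4 libraries compared or without MEF10 MyoD+FRG replicate 2, and every alternative to the class shares were chosen after seeing the data. The differing-region counts of the 10 main comparisons stayed within 1.5 times with autosomes alone, with the stricter overlap and with regions merged from the 4 libraries compared. The log2 ratio of quiescent-only to activated-only shares in GFP against unsorted Dox+FRG cells kept its direction and its side of the threshold in every alternative run, from 1.04 to 2.67. Depth is unknown, so no alternative corrects for it. The random draws lower counts by their own construction, and for other changes the cause was not tested. The planned choice of the highest-scoring peaks and the planned gene, motif and promoter alternatives were not run.

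Differing regions with extended peaks, with the same number of peaks drawn (where moved over 1.5 times) and with the same number of extended peaks drawn were 4024, 17944 and 1193 for Dox+FRG day 8 against day 0, 4487, 18635 and 1233 for day 10 GFP, 13005, 15255 and 853 for Dox day 8 and 26318, 14920 and 815 for FRG day 8 against day 0. They were 13284, 14599 and 987 for Dox+FRG against Dox day 8, 2534, 16020 and 1138 for day 10 GFP against activated and 2411, 14798 and 1093 against quiescent satellite cells, and 1728, 11656 and 396 for the MEF10 groups. Extended peaks and their draw gave 1240 and 882 for day 8 GFP against unsorted cells, and 2250 and 1163 for activated against quiescent satellite cells.

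Leaving out 1 library gave 45390 to 50461 differing regions for Dox+FRG day 8 against day 0, 16647 to 26461 for day 8 GFP against unsorted cells, 47591 to 51892 for day 10 GFP, 58159 to 73261 for Dox and 66288 to 72933 for FRG against day 0, and 46764 to 67172 for Dox+FRG against Dox day 8. It gave 33700 to 39471 and 28254 to 32551 for day 10 GFP against activated and quiescent satellite cells, 28620 to 36420 between these, and 32821 to 49155 for the MEF10 groups.

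The relation of activated satellite cell regions with day had r of 0.75 without day 8 (permutation p = 0.0380) and 0.47 to 0.63 without 1 replicate number. That of day 0 regions had r of -0.84 with equal list lengths (permutation p = 0.00845) and -0.94 to -0.74 without 1 replicate number, but -0.38 with extended peaks (permutation p = 0.340). Pairing by replicate number stays open, with 1 of 45 correlations of deviations over 0.1. With the replicate number as a block, r was 0.55 (permutation p = 0.121) and -0.85 (permutation p = 0.0312). No paired analysis was possible for the differing regions because these counts come from no test.

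Dox+FRG minus Dox with extended peaks was -38.0 points for fibroblast-only regions, -1.19 for log2 fibroblast-only over activated-only and -0.59 for log2 quiescent-only over activated-only, each with an exact permutation p of 0.0286. With equal list lengths fibroblast-only regions shrank to -2.26 points (exact permutation p = 0.429), and activated-only regions reversed to 6.74 points and the log2 quiescent-only ratio to 0.048. With equal numbers of extended peaks fibroblast-only regions reversed to 3.64 and activated-only regions to 15.3 points. On the classes of the deposited lists, extended peaks gave -4.31 points for fibroblast-only and -13.1 for activated-only regions, a log2 fibroblast-only ratio of -0.16 and a reversed log2 quiescent-only ratio of 0.32. Equal list lengths gave -3.47 points for fibroblast-only regions (exact permutation p = 0.286) and 6.73 for activated-only regions (reversed). Equal numbers of extended peaks gave -0.137 points for fibroblast-only and -0.291 for activated-only regions, a log2 fibroblast-only ratio of -0.041 and a reversed log2 quiescent-only ratio of 0.61. Without 1 library these differences were -28.3 to -17.4 points (fibroblast-only), -25.0 to -20.3 points (activated-only), -1.06 to -0.56 (log2 fibroblast-only ratio) and -0.35 to 0.10 (log2 quiescent-only ratio, reversed without Dox+FRG day 4 replicate 2).

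GFP minus unsorted fibroblast-only regions, past an unadjusted 0.05 in the deposited lists, were -7.67 points with equal list lengths (exact permutation p = 0.0424), -4.23 with equal numbers of extended peaks (exact permutation p = 0.0869) and, on the classes of the deposited lists, -0.538 with extended peaks and -0.242 with equal numbers of them, no longer past it. Without 1 library they were -14.6 to -9.89 points and missed an unadjusted 0.05 in 6 of 12 cases (exact permutation p of 0.0576 to 0.0909), which were day 2 replicate 2, day 4 replicate 1 and each of the GFP libraries. Satellite-shared regions were then 9.89 to 16.4 points. They differed by 8.02 points with extended peaks, 6.96 with equal list lengths, and 0.769 and 1.42 with extended peaks and equal numbers of them on the classes of the deposited lists, but by 14.4 points with equal list lengths on the classes of the deposited lists (exact permutation p = 0.0121). FRG minus Dox+FRG day 8 fibroblast-only regions were 72.3 points with extended peaks, 11.9 with equal list lengths and -3.40 (reversed) with equal numbers of extended peaks, and on the classes of the deposited lists 24.0, 13.8 and 1.21 points. FRG lists kept 42643 and 42714 extended peaks and Dox+FRG day 8 lists 6181 and 3646.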

Other observations

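All tests here were chosen after the shares had been seen, except the overlap of FRG and day 10 GFP regions, whose bounds were set before it was computed. Peaks on chromosome X made up 2.15% ± 0.0377 of day 0 lists (SD, n = 2), 2.30% ± 0.0889 of 8 unsorted Dox+FRG lists, 2.59% ± 0.0622 of 4 GFP lists and 2.61% ± 0.0787 of 4 satellite cell lists. GFP and unsorted lists differed by 0.289 percentage points (exact permutation test over 495 splits, p = 0.00202). This test also permuted the 2 libraries of a group as separate units, and days differed between the sides. Dox lists of days 4 and 8 were at 2.34% to 2.51% and FRG lists at 2.41% and 2.44%. Shares above the unsorted Dox+FRG mean thus occurred without a GFP label too. The GFP lists, at 2.52% to 2.67%, still lay above every other fibroblast-derived list, the highest being Dox day 8 replicate 2 at 2.51%. Of the regions gained in day 10 GFP cells against day 0, 2.89% lay on X, against 1.83% of those lost. Fibroblast-only regions were on X at 1.71%, quiescent-only regions at 2.75%, activated-only at 2.60%, satellite-shared at 2.24% and common regions at 2.65%.

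GFP cells had a higher ratio of quiescent-only to activated-only regions than unsorted Dox+FRG cells. The log2 difference was 1.34 with the same number of peaks drawn from each library and 1.04 with equal numbers of extended peaks. Such draws thin both classes alike and so nearly keep a ratio, with 1.86 on the classes of the deposited lists against 1.88 undrawn. They cannot decide whether list length contributed, which stays open. GFP lists held 43467 to 64947 peaks and unsorted Dox+FRG lists 46017 to 70877, so the ranges overlapped. Weak peaks near the authors' threshold are argued against only as far as peak width follows strength, with a difference of 1.45 for extended peaks. Whether sorting itself may give such regions stays open, because the labels do not state which cells were sorted, although FRG libraries without a GFP label called 37.8% of quiescent-only regions. A hypothesis that cells with an active Pax7 reporter resemble quiescent cells in this respect was not tested. At day 8, GFP and unsorted cells differed more in activated-only (24.2% and 55.4%) than in quiescent-only regions (22.2% and 17.0%).

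FRG day 8 cells, which had no doxycycline, called quiescent-only regions more often than activated-only ones, with a log2 ratio of 0.87 ± 0.01 (SD, n = 2). FRG stood 1.72 above Dox day 8 with the same number of peaks from each library and 1.48 above with equal numbers of extended peaks. These draws too thin both classes alike, so they do not decide whether list length contributed, which stays open. Whether weak peaks account for part of the ratio stays open. It was 0.27 with extended peaks, but 1.32 with extended peaks on the classes of the deposited lists. FRG and day 10 GFP libraries called 1941 and 1773 of the 5637 quiescent-only regions in both libraries and shared 741, which is 1.21 times the 610.5 of independent sets and lies between the bounds set for an overlap (1.5) and for none (1.1), so that test left the question open.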
